A study of Homo sapiens with 8 samples.

How the data were processed

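The series comprised 8 total RNA libraries of SW480 cells, 2 for each combination of shRNA (control or RBMS1) and time of alpha-amanitin (0 h or 9 h), depleted of ribosomal RNA and made with a ScriptSeq kit, per the labels' protocols. The series text names 2 shRNA clones against RBMS1, the labels a single knockdown group, so which clone was used, or whether both were pooled, is unknown. Nothing in the labels said that the libraries of a group came from separate cultures. STAR 2.5, Cufflinks, Cuffdiff and the build hg38 are named in the submitters' processing notes, without roles or order, and versions of Cufflinks and Cuffdiff are not given in the sources used here. The authors deposited 2 tables, 1 for each shRNA, with a RefSeq accession and a log fold change per transcript, per the file headers. The values were treated as log2 fold changes because Cuffdiff, named in the submitters' processing notes, writes log2; neither the base nor the direction is in the headers of the deposited tables. The direction, 9 h over 0 h, was read from negative values of MYC, FOS and JUN, mRNAs known for rapid turnover. How the authors normalised the libraries is not stated. The deposited tables hold 1 value per transcript with the libraries already combined, and no counts, abundance, p-values or columns per library. All values lie within ±10 and none is exactly 0, so transcripts were left out upstream by a rule that is not stated. The depth per sample is therefore unknown, and no interval that needs it is given. The precision of single values could not be assessed, and transcripts with few reads cannot be recognised.

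The control table held 21328 transcripts (18822 coding and 2506 non-coding accessions) and the table of knockdown cells held 20474 (18117 and 2357). Of 22468 accessions in either table, 22132 were paired with a symbol by the RefSeq gene table (assembly GRCh38.p14) and 204 by GENCODE release 29; 132 stayed without a symbol and were left out. A gene's value was the mean over its transcripts, and for the difference over the transcripts in both tables, which gave 12479 genes, 8072 with 1 listed transcript and 4407 with several. For the latter the median SD of the difference among transcripts of a gene was 0.68. The difference was the knockdown value minus the control value, centred by subtracting its median over all genes (−0.0168). A size of 1 on the log2 scale (2-fold) was counted in each direction, without a test.

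The main tests, the gene lists, most alternatives and the rule for named genes were fixed before the data were examined. Chosen after seeing the data were the restriction to 1 listed transcript, medians over transcripts, matching on coding length and GC content, transcript-level motif values, and, for lists, leaving out the outer 1% and taking the least changing transcript. So were the tests on chromatin regulators, fastest-decaying genes, large differences and 5-mers. The 24 lists were immediate early and short-lived regulators, cytosolic ribosomal proteins, the nuclear-encoded respiratory chain, glycolysis, mitochondrially encoded genes, RNA polymerase III transcripts, snoRNA host genes, ZNF genes, p53 targets, Wnt targets and intestinal stem cell genes, colon epithelial genes, mesenchymal and motility genes, markers of other cell types, interferon response, unfolded protein and integrated stress response, cholesterol biosynthesis, mitosis and G2/M genes, DNA replication, replication-dependent histones, mRNA decay machinery, RNA polymerase II subunits, RNA-binding proteins of AU-rich and U-rich elements, proteasome subunits, and the reported RBMS1 targets. A list's median was placed among 10000 random lists of the same size, unmatched for decay and matched on the mean of both log2 fold changes in 10 bins for the difference. The tail share was counted on both sides and adjusted over the lists by the Benjamini-Hochberg method, and a list was called where the adjusted share was under 0.05 and the percentile outside 2.5 to 97.5. Such percentiles describe these libraries and are not tests over replicates. Some genes belong to more than one list.

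For motifs, the longest 3′UTR among a gene's listed coding transcripts was taken from GENCODE release 29 (GRCh38, the assembly of hg38), of at least 20 nt, for 10968 genes, 97.0% of the 11302 protein-coding genes in both tables. The fixed design called for the 3′UTR of the named transcript, and the gene-level choice was made because values were averaged per gene; transcript-level values were run as an alternative. Random lists were matched on 3′UTR length (10 bins) and A+T content (5 bins). Other sites with the same bases served as controls.

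Genes named were those fixed beforehand (RBMS1, RBMS2, RBMS3, AKAP12, SDCBP, POLR2A and MYC), the 12 protein-coding genes with the largest and the 12 with the smallest centred difference, the 8 lowest and 8 highest by the mean of both tables, and in each list the 2 members with the largest and the 2 with the smallest difference and the 2 lowest and 2 highest in control cells. ZNF and olfactory receptor genes (outside their list), placeholder symbols (LOC, LINC, KIAA, FAM, TMEM, HCG and open reading frame names), Y-linked genes and XIST were left out of the ranked genes. Some genes that the rule takes are not reported here. Coordinates are those of the RefSeq gene table.

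The procedures were tested on simulated data. With the real differences shuffled over 12479 genes and 200 genes changed by 2 on the log2 scale, 94.5% of the changed genes were recovered past 1, and 9.02% of the others lay past 1 too. Of 50 lists of 60 genes, 4% lay outside the central 95% with no shift added, 68% with a shift of 0.1 and 100% with 0.2 or 0.4. These shares are before the adjustment over lists that a call also needs, so they do not show how many would be called. For the difference by 3′UTR motif over 10968 genes, ATATA lay at the percentile 9.85 with no shift, 88.2 with a shift of 0.02 and 100 with 0.05, and other orders reached 93.2, 98.9 and 99.2 in the same data. Alternatives covered the centring, the size threshold, the scale, the choice of transcript, the gene set, the matching of random lists and the motif. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.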

Results

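Transcript stability was measured in SW480, an established human colorectal adenocarcinoma line, stably expressing either a control shRNA or an shRNA against RBMS1, an RNA-binding protein of single-stranded nucleic acids. The series description lists 2 RBMS1 shRNA clones, and which of them the knockdown libraries carried, or whether they were pooled, is not given. Transcription was blocked with alpha-amanitin at 10 µg/mL, a mushroom toxin that binds RNA polymerase II, and total RNA was sequenced at 0 h and 9 h. The 4 groups held 2 libraries each, 8 libraries in all. The values used here were the authors' comparisons of 9 h with 0 h, 1 log2 fold change per RefSeq transcript and cell population. Read depth and the spread between libraries were unknown, so no difference of a single gene could be set against replicate error and no p-value was given for any gene. The control table held 21328 transcripts, the knockdown table held 20474, and 19334 were in both. These gave 12479 genes with a value in both cell populations. A gene's value was the mean over its transcripts, over those in both tables where the cell populations are compared or a gene is named, and negative values mean a lower level at 9 h. The direction of the comparison and the log base were not stated in the tables, and were taken as described in the processing.

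The first comparison asked which transcripts were lost after the transcription block in control cells. Replication-dependent histone mRNAs, which end in a stem-loop, had the lowest median of the 23 gene lists with measured members, at −1.69, and 50 of 57 lay at −1 or below. Wnt targets and intestinal stem cell genes followed with a median of −1.14 over 23 genes, 13 of them at −1 or below. Immediate early and other short-lived regulators had a median of −0.76 over 50 genes, with 22 at −1 or below. The 427 ZNF genes had a median of −0.57. Their list took every symbol that starts with ZNF and a digit, mostly zinc-finger transcription factors, without leaving out non-coding genes. Mitosis and G2/M genes lay at −0.40 over 38 genes. In the authors' deposited table for the control shRNA, BAMBI, an inhibitor of TGF-beta signalling, was at −2.77, AXIN2, a negative regulator of Wnt signalling, at −1.89, KLF2 at −2.93, DUSP6, an ERK phosphatase, at −2.08, MYC at −1.44 and histone H1-3 at −3.81. At the other end, mRNAs of the nuclear-encoded respiratory chain had a median of 0.45 over 76 genes, cytosolic ribosomal proteins 0.41 over 79 genes, RNA polymerase II subunits 0.40 over 12 genes, glycolytic enzymes 0.36 over 18 genes and proteasome subunits 0.27 over 34 genes. Transcripts of RNA polymerase III, an enzyme less sensitive to alpha-amanitin, had a median of 0.48 over 14 genes, all 14 above 0. In the authors' deposited table, RNY5 was at 1.54, RNY4 at 1.55, RPL7 at 1.00 and ALDOC at 0.76.

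Each of these 11 lists stood outside 95% of 10000 random lists of the same size after adjustment over the lists. The histone, Wnt, immediate early and ZNF medians lay below all random lists and the ribosomal protein and respiratory chain medians above all of them, with an adjusted tail share of 0.000767 each, the smallest the random lists could give. The sign of the tables was itself set from MYC, FOS and JUN, members of the immediate early list, so the side on which that list lies is not an independent finding. The adjusted tail share was 0.00394 for RNA polymerase III transcripts, 0.0092 for the proteasome, 0.0164 for glycolysis, 0.023 for mitosis and 0.0255 for RNA polymerase II subunits. The scale of total RNA is undetermined after a transcription block, and values above 0 are relative to the rest of the library. Set relative to ribosomal protein mRNAs, the median of all genes shifted from −0.07 to −0.48, and the medians of glycolysis at −0.05, of RNA polymerase II subunits at −0.01 and of the proteasome at −0.14 changed sign, whereas the respiratory chain at 0.04 and RNA polymerase III transcripts at 0.06 stayed above 0.

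Among the lists that did not pass, snoRNA host genes had a control median of −0.41 over 24 genes at the percentile 1.65 and an adjusted tail share of 0.0636. In the authors' deposited table the transcripts of SNHG3 were at −4.57 and −0.11 and SNHG9 at 1.91. Mesenchymal and motility genes lay at 0.19 over 30 genes, with an adjusted tail share of 0.0881, and the actin-binding protein TAGLN was at 2.70 in the authors' deposited table while TGFB2 was at −1.61, with a transcript in that table alone at 0.78. The control medians were −0.22 for 24 p53 targets, −0.16 for 17 colon epithelial genes, −0.15 for 31 genes of the unfolded protein and integrated stress response, −0.11 for 27 interferon response genes, 0.13 for 25 cholesterol biosynthesis genes and 0.05 for 45 DNA replication genes. The intestinal transcription factor CDX2 was at −2.06 and the epithelial adhesion protein EPCAM at 0.40 in the authors' deposited table. The mRNA decay machinery had a control median of −0.16 over 60 genes and RNA-binding proteins of AU-rich and U-rich elements a median of −0.22 over 41 genes. Of the markers of fibroblasts, immune, endothelial, blood and liver cells, ACTA2, LYZ and CD68 were measured in both tables, and the median of these 3 was 0.21 in control cells. No mitochondrially encoded gene was in either table.

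In the RBMS1 knockdown cells the same question gave the same 11 lists, 5 lower and 6 higher. Histone mRNAs had a median of −1.67, with 51 of 57 at −1 or below, Wnt targets −0.92 over 22 genes, immediate early genes −0.65 over 51 genes, ZNF genes −0.55 over 433 genes and mitosis genes −0.40. The respiratory chain was at 0.39, ribosomal proteins at 0.38, RNA polymerase II subunits at 0.37, glycolysis at 0.29, the proteasome at 0.27 and RNA polymerase III transcripts at 0.41 over 13 genes. The adjusted tail share was 0.000767 for the histone, Wnt, immediate early, ZNF, ribosomal protein and respiratory chain lists, 0.0158 for mitosis, 0.0172 for the proteasome, 0.0199 for RNA polymerase III transcripts, 0.0345 for RNA polymerase II subunits and 0.0464 for glycolysis. Relative to ribosomal protein mRNAs the median of all genes was −0.43, glycolysis lay at −0.08, RNA polymerase II subunits at −0.01 and the proteasome at −0.11, so these again changed sign. The knockdown medians of lists that did not pass were −0.19 for snoRNA host genes, −0.28 for p53 targets, 0.09 for 13 colon epithelial genes, 0.14 for mesenchymal genes, 0.13 for 4 markers of other cell types, 0.02 for interferon response genes, −0.10 for stress response genes, 0.04 for cholesterol biosynthesis, 0.03 for DNA replication, −0.01 for the decay machinery and 0.04 for RNA-binding proteins.

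**Figure D1:**
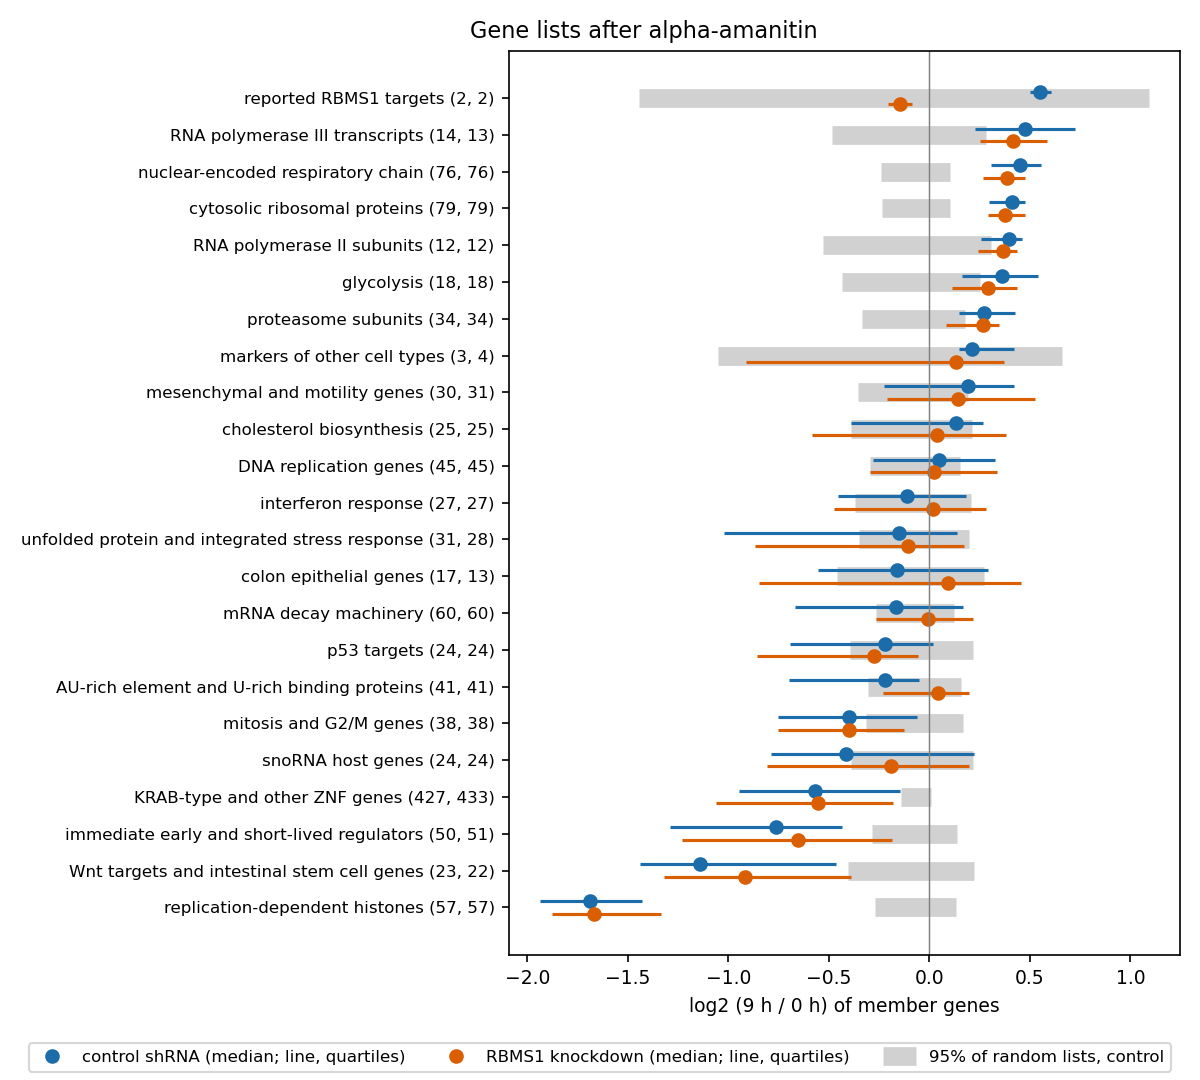
Log2 ratio of 9 h over 0 h for 23 gene lists in control (blue) and RBMS1 knockdown cells (orange). Points are medians over member genes, lines their quartiles, grey bars the range holding 95% of random lists from the control table, and brackets give the genes measured in control and knockdown; histone mRNAs sit lowest in both, at −1.69 and −1.67.

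Over all genes, control cells had a median of −0.07 with quartiles −0.52 and 0.31 over 13090 genes, and 1396 genes (10.7%) lay at −1 or below against 633 (4.84%) at 1 or above. Knockdown cells had a median of −0.05 with quartiles −0.47 and 0.31 over 12785 genes, and 1214 genes (9.5%) lay at −1 or below against 672 (5.26%) at 1 or above. With ribosomal protein mRNAs as the reference, the split was 2917 lower and 366 higher in control cells and 2409 lower and 408 higher in knockdown cells. By the mean of both cell populations the lowest protein-coding genes were FOXA2, DRC2, DUSP18, DYRK1B, RSC1A1, MCM2, BCKDHA and ZBTB22, and the highest TSPOAP1, ST3GAL5, PEX11G, DCP2, MPP3, XPNPEP1, YTHDC1 and IL18BP. In the authors' deposited tables, FOXA2, a forkhead transcription factor, was at −7.91 in control and −8.58 in knockdown cells, while a transcript in the knockdown table alone was at 1.90. Of the DCP2 transcripts, which encode a decapping enzyme of mRNA decay, one was at 9.15 in control and 9.28 in knockdown cells and the other at −0.41 and −0.65 in the authors' deposited tables. For MCM2, a subunit of the replicative helicase, the coding transcript was at 0.16 and 0.20 in the authors' deposited tables, and a non-coding one at −9.48 and −8.82 put the gene among the lowest.

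The decay profiles of control and knockdown cells were compared next. MYC was at −1.44 in control and −1.38 in knockdown cells in the authors' deposited tables, BAMBI at −2.77 and −2.82, CDX2 at −2.06 and −2.01, DUSP6 at −2.08 and −2.01 and H1-3 at −3.81 and −3.78. Across 12479 genes, Pearson's r was 0.50, Spearman's rho 0.66 and the slope of the major axis 1.00, and 78.2% of genes had the same sign. Of the 500 lowest genes of each cell population, 210 were shared, where 20.03 were expected of independent lists. Genes are not independent replicates, and no test was attached to these values.

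**Figure D2:**
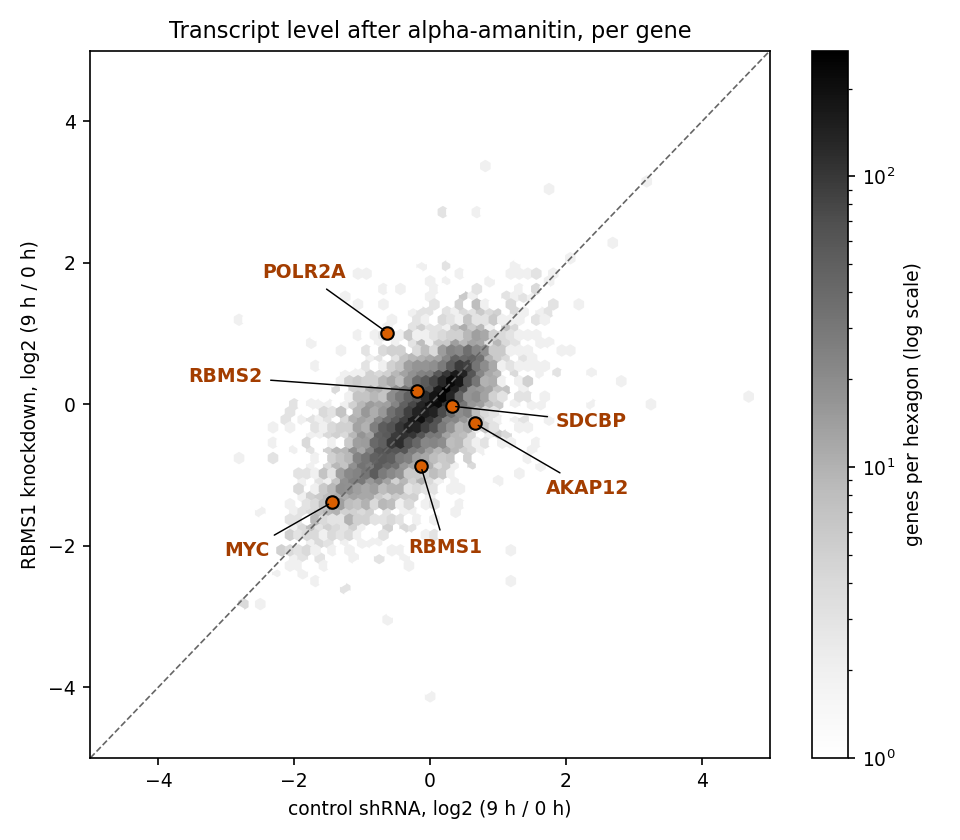
Log2 ratio of 9 h over 0 h per gene in control cells (x axis) and RBMS1 knockdown cells (y axis), as genes per hexagon on a log grey scale, with 6 genes fixed beforehand as orange points and equal values as the dashed line. MYC lies near the line at −1.44 and −1.38, RBMS1 and AKAP12 below it and POLR2A above it; 30 of the 12479 genes lie beyond 5 in either direction and are not drawn.

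RBMS1 itself (chromosome 2, 160272151 to 160493807, GRCh38) was at −0.14 in control and −0.87 in knockdown cells as the mean of 2 transcripts in the authors' deposited tables. The centred difference of RBMS1, knockdown minus control after subtracting the median difference of all genes, was −0.71, and −0.43 and −0.997 for its transcripts taken singly. A ratio of 9 h to 0 h within one cell population does not measure how much RBMS1 was left before the block, so the tables held no check of the knockdown. Its paralog RBMS2 had a centred difference of 0.40, from −0.19 in control and 0.19 in knockdown cells in the authors' deposited tables, and RBMS3 was not among the genes with a value in both. AKAP12 (chromosome 6, 151239967 to 151358559), a scaffold protein of protein kinase A, was at 0.65 in control and −0.27 in knockdown cells in the authors' deposited tables, a centred difference of −0.91 from 1 transcript. SDCBP (chromosome 8, 58553261 to 58582858), the scaffold protein syntenin, had a centred difference of −0.33, from 0.32 and −0.03 as means over the authors' deposited tables, but its 3 shared transcripts ran from −0.87 to 0.34. AKAP12 and SDCBP were remembered as reported RBMS1 targets from work that used these samples, so their direction is not independent evidence. Their median of −0.62 lay at the percentile 1.72 of matched random lists, with an adjusted tail share of 0.199. The percentile was 6.52 with unmatched random lists, 6.6 with matching on 3′UTR length, 4.42 with matching on coding length and GC content, and 10.14 at a median of −0.28 with the least changing transcript of each gene. The mRNA of POLR2A (chromosome 17, 7484366 to 7514616), the RNA polymerase II subunit that alpha-amanitin binds, was at −0.63 in control and 1.01 in knockdown cells in the authors' deposited tables, a centred difference of 1.66 from 1 transcript, the highest of the 12 measured subunits.

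The main question of the series was whether transcript stability differed on RBMS1 knockdown. Most genes differed little, and 11352 of 12479 (91.0%) had a centred difference under 1 in size, with quartiles of −0.19 and 0.23. A centred difference of 1 or more was found for 608 genes (4.87%) and of −1 or less for 519 (4.16%). Among the 12 protein-coding genes with the largest values were MRPL58, PLIN3, DYRK1B, PGPEP1, DTNBP1, LYRM7, TENT4A, CYB561D1, ACSF3 and STK31. The shared transcript of DYRK1B, a kinase, was at −8.72 in control and −0.58 in knockdown cells in the authors' deposited tables, while its other transcripts, in the control table alone, were at 1.69 and −2.65. STK31 was at −1.01 and 4.51 in the authors' deposited tables. The 12 with the smallest values were DRC2, RSC1A1, TSPOAP1, DUSP18, BBS9, FGFR4, ST3GAL5, PEX11G, PHETA1, EHF, MXD1 and ZBTB14. The shared transcript of FGFR4, a receptor tyrosine kinase, was at 4.31 in control and −3.13 in knockdown cells in the authors' deposited tables, while another, in the knockdown table alone, was at 8.31. ST3GAL5, a ganglioside sialyltransferase, was at 8.71 and 1.64 in the authors' deposited tables, with a further transcript at −0.94 in knockdown cells alone. The lowest of these values, −9.98 for DRC2 in knockdown cells in the authors' deposited table, lies at the limit of the tables, where every value is within ±10. Another DRC2 transcript, listed for knockdown cells alone, was at 0.91 in the authors' deposited table. Of these 24 genes, 12 had several transcripts, and in all 12 the transcripts differed by 1 or more in the size of their difference. MRPL58, which encodes a mitochondrial ribosomal protein, was such a gene, with a centred difference of 8.38 as a mean of transcripts at −0.21 and 16.96. Among the 8072 genes with 1 listed transcript, 274 lay at 1 or above and 205 at −1 or below. Without replicate values, none of these differences could be called.

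Of the 23 lists with measured members, none was called higher or lower in the knockdown after adjustment, and 4 had an unadjusted tail share under 0.05. RNA-binding proteins of AU-rich and U-rich elements, which act on mRNA stability, had a median centred difference of 0.15, with 33 of 41 above 0 and 5 at 1 or above. As means over shared transcripts of the authors' deposited tables, HNRNPD was at −1.34 in control and 0.19 in knockdown cells, ELAVL2 at −0.97 and 1.73, and CPEB4, on the other side, at 0.86 and 0.02. ZFP36L2, with 1 transcript, was at −1.97 and −0.50 in the authors' deposited tables. RBMS1 itself is a member of this list. The mRNA decay machinery had a median of 0.12, with 37 of 60 above 0. The deadenylation factor TOB1 was at −0.18 in control and 1.92 in knockdown cells in the authors' deposited tables, with a further transcript at 2.16 in control cells alone. CNOT10, a subunit of the CCR4-NOT deadenylase, was at 1.22 and −0.29 as the mean of 2 transcripts in the authors' deposited tables. ZNF genes had a median of −0.05, with 176 of 418 above 0. Their percentiles were 99.5, 99.3 and 0.2, with adjusted tail shares of 0.103, 0.103 and 0.0966. The reported RBMS1 targets were the other list. ZNF genes were called lower against unmatched random lists and without the outer 1% of values, at adjusted tail shares of 0.023 and 0.0276. The 360 ZNF genes with an annotated 3′UTR had a smaller median, of −0.03, and lay at the percentile 11.7 with matching on coding length and GC content, at an adjusted tail share of 0.701, and at 3.16 with matching on 3′UTR length. The smaller median came from the members left. Over these same 360 genes, random lists had a median of −0.0012 with matching on 3′UTR length and −0.0147 with coding length and GC content. The matching thus moved the percentile as well. These 360 genes were not run with the main matching, so how much of the change each made is unknown. By the mean of all 418 members, ZNF genes lay at the percentile 14.8. The decay machinery was called higher without the outer 1%, at 0.0276, and RNA-binding proteins among genes with 1 listed transcript, at 0.0176 over 14 genes. With the least changing transcript of each gene, the median of RNA-binding proteins was 0.06, at the percentile 89.8.

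The remaining lists had unadjusted percentiles inside the central 95%. Immediate early genes had a median centred difference of 0.09 at the percentile 93.8, and of 99.2 with matching on coding length and GC content, where the adjusted tail share was 0.113. Among them EGR3 was at 2.01 and ATF3 at −1.17, a mean of transcripts at 0.09 and −2.43. A further EGR3 transcript, listed for control cells alone, had a log2 fold change of 0.58 in the authors' deposited table. Wnt targets had a median of 0.08, with the cyclin CCND1 at −0.95 and the ephrin receptor EPHB2 at 0.84, a mean of transcripts at −0.30 and 1.98. The medians were 0.07 for colon epithelial genes, 0.06 for histones, 0.05 for glycolysis, 0.05 for the interferon response, 0.04 for mitosis genes, 0.03 for p53 targets and 0.01 for RNA polymerase II subunits. They were −0.0010 for DNA replication, −0.0011 for snoRNA host genes and −0.0029 for cholesterol biosynthesis. The medians were −0.02 for mesenchymal genes, −0.03 for ribosomal proteins, −0.03 for the respiratory chain, −0.05 for the proteasome, −0.06 for the stress response, −0.12 for markers of other cell types and −0.13 for RNA polymerase III transcripts. Single members lay further out. Among mesenchymal genes the transcription factor SNAI2 had a centred difference of 1.24 and the integrin ITGA2 −2.58, a mean of transcripts at −0.39 and −4.77. In cholesterol biosynthesis IDI1 was at −0.29 and LSS at 1.38, a mean of 4 transcripts from −0.07 to 4.32. Of the stress response the amino acid transporter SLC7A5 was at −0.75 and XBP1 at 1.34, a mean of transcripts at −0.33 and 3.01.

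**Figure D3:**
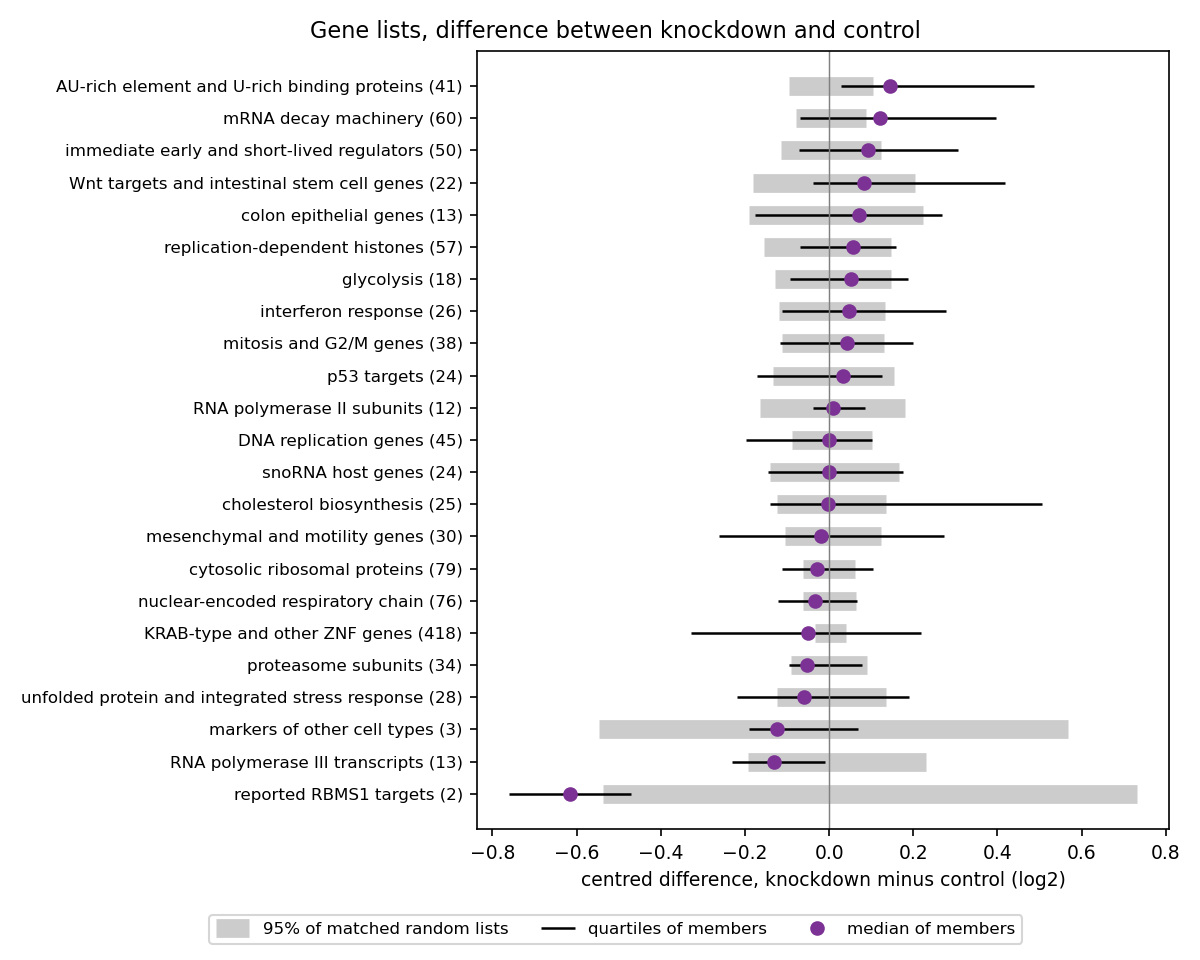
Centred difference (knockdown minus control, log2) for 23 gene lists, with the number of genes in brackets. Points are medians over member genes, black lines their quartiles and grey bars the range holding 95% of random lists matched on the mean of both log2 fold changes; RNA-binding proteins and decay machinery lie above the bar, ZNF genes and the reported RBMS1 targets below it, and none passed the adjustment.

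RBMS1 is known from binding assays to prefer the RNA sequence AUAUA, so 3′UTRs with ATATA were compared with the rest. The 6415 genes with ATATA had a median centred difference of −0.0127 and the 4553 without it 0.0194. Random lists matched on 3′UTR length and A+T content had a median of −0.0094, and the observed value lay at their percentile 5.79, the lowest of the 10 orders of 3 A and 2 T. The other orders lay between the percentiles 15.6 and 88.3, and the adjusted tail share of ATATA was 0.651. The longer site ATATAG, in 2841 genes, lay at the percentile 1.66, before any adjustment, with a median of −0.0191 against −0.0114 in random lists. Other settings placed ATATA at the percentile 39.7 among genes with 1 listed transcript, 8.38 at the transcript level, 29.2 in coding sequences, 5.94 with the shortest 3′UTR and 6.395 with the residual along the major axis. The 4760 genes with at least 2 ATATA lay at 2.545. In contrast, known destabilising sites stood apart in the decay of control cells. The Pumilio site, in 2826 genes, had a median of −0.27 against −0.15 in matched random lists, and TATTTAT, an AU-rich element, −0.20 against −0.15, both below all random lists. The core ATTTA lay at the percentile 1.24. In the knockdown cells the Pumilio site was at −0.24 and TATTTAT at −0.19, again below all random lists, and ATTTA at the percentile 1.475. These sites had been fixed beforehand for the decay of control cells alone. In the difference, genes with a Pumilio site lay at the percentile 99.3, before any adjustment, at 0.0009 against −0.0092. Genes with TATTTAT lay at 84.1 and those with ATTTA at 43.1.

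Genes with long coding sequences had lower values at 9 h in both cell populations. Across 10968 genes, Spearman's rho of coding length was −0.24 with the control values, −0.16 with the knockdown values and 0.13 with the difference. Of 10 bins of genes by coding length, the one with the longest coding sequences, at a median of 4452 nt, lay at −0.37 in control and −0.21 in knockdown cells, a median centred difference of 0.13. The bin with the shortest, at 375 nt, lay at 0.24 and 0.20, with a median centred difference of −0.04. For the difference, rho was 0.10 with exon count, 0.10 with GC content, 0.09 with transcript length and 0.01 with 3′UTR length. For 3′UTR length it was −0.18 in control and −0.18 in knockdown cells, for transcript length −0.26 and −0.21, for exon count −0.02 and 0.04 and for GC content 0.06 and 0.12. These correlations are across genes of the same libraries and carry no test.

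**Figure D4:**
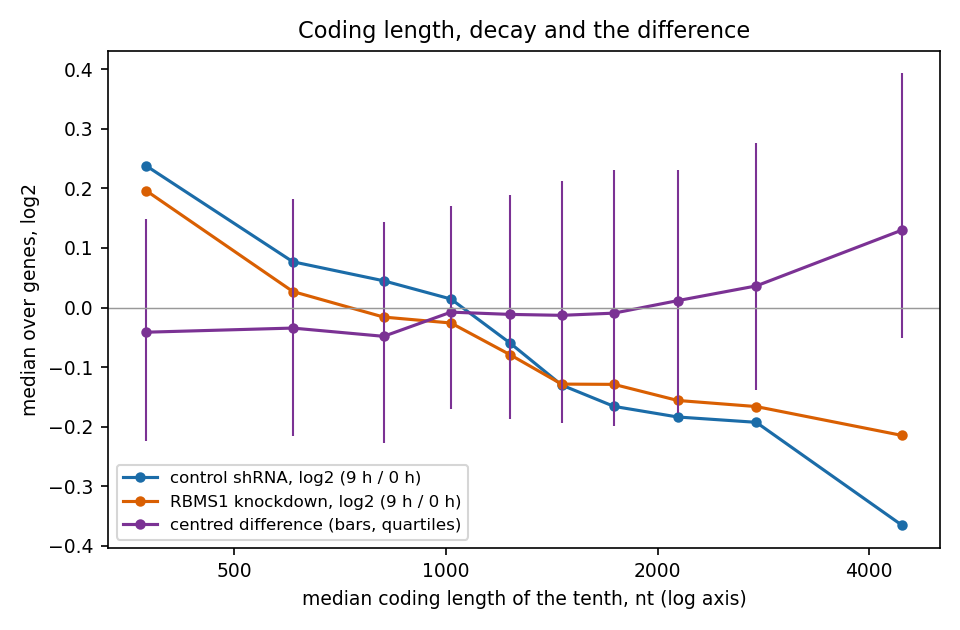
Median log2 ratio of 9 h over 0 h in control (blue) and knockdown cells (orange) and median centred difference (purple, bars are quartiles over genes) for genes in 10 bins of coding length, on a log axis in nt. The difference runs from −0.04 at 375 nt to 0.13 at 4452 nt, with quartiles of genes that overlap throughout.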

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

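The restrictions to genes with 1 listed transcript, the medians over transcripts, the matching on coding length and GC content, the transcript-level motif values and, for lists, the exclusion of outer values and the choice of the least changing transcript were chosen after seeing the data. Centring, the major axis residual, quantile normalisation and protein-coding genes alone kept the counts of genes past 1 within 1.5 times. For 44 named genes, 312 of 352 values under the alternatives stayed close, 28 moved and 12 changed sign; the transcripts of a gene disagree, which the choice of transcript shows directly. With the transcript of smallest change, the difference became 0.56 for EHF, −0.30 for EPHB2, −0.076 for LSS, −0.78 for LYRM7, −0.21 for MRPL58, 1.79 for MXD1, −2.54 for PGPEP1, 1.70 for PHETA1 (1.71 with the first accession), −1.25 for PLIN3, 0.34 for SDCBP and −4.89 for TENT4A. Genes higher and lower in the difference numbered 1272 and 1120 at 1.5-fold, 207 and 186 at 4-fold, and 274 and 205 with 1 listed transcript. In that last setting fewer genes were compared, 8072 against 12479, and the share past 1 was lower too, at 5.93% against 9.03%. With the first accession 845 were higher and 808 lower. In control cells 2925 genes were lower and 1449 higher at 1.5-fold, 324 and 204 at 4-fold, and 2917 and 366 relative to ribosomal protein mRNAs. In knockdown cells these were 2598 and 1423, 279 and 201, and 2409 and 408. Pearson's r between the profiles was 0.62 with 1 listed transcript, where the cause was not tested. The shared genes numbered 57 among the 200 lowest and 512 among the 1000 lowest. In the difference 1 list was called with unmatched random lists, 1 with 1 listed transcript and 2 without the outer 1%; the cause was not tested. The median of genes with ATATAG minus that of matched random lists was −0.0078, past the percentile that ATATA did not pass; the cause was not tested. Against protein-coding genes 10 decay lists were called in place of 11, as RNA polymerase III transcripts had no members there. No paired analysis was possible because the tables hold 1 fold change per transcript and no columns per library; leaving out replicates, the replicate block and the abundance filter were not run for the same reason, and the filter on values at 0, infinite or at a ceiling was not run because none was found. Depth is unknown, so what it limits could not be shown.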

Other observations

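The groups of non-coding RNAs and chromatin regulators and the tests on coding length, single transcripts, the fastest-decaying genes, large differences and 5-mers were chosen after the data had been seen. Non-coding accessions lay higher at 9 h than coding ones, with transcript medians of 0.14 in control and 0.15 in knockdown cells against −0.06 and −0.05. They include non-coding transcripts of protein-coding genes, such as MCM2. The 23 Cajal body RNAs, which guide RNA modification, had medians of 0.48 and 0.54, with 1 and 2 members below 0. The 93 H/ACA box snoRNAs lay at 0.36 and 0.26, with 14 and 18 below 0, and the 121 C/D box snoRNAs at 0.30 and 0.32, with 45 and 32 below 0. The 4 spliceosomal U RNAs lay at 0.27 in control, with 0 below 0, and −0.21 in knockdown cells, with 2 below 0. Antisense RNAs (267) had medians of 0.18 and 0.16, long intergenic RNAs (108) 0.19 and 0.16, and divergent transcripts (85) 0.12 and 0.15. The 37 microRNA loci lay at −0.05 in control and 0.25 in knockdown cells, with 19 and 9 members below 0, and this difference was not tested.

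Chromatin regulators were taken as families that include histone acetyltransferases, methyltransferases, demethylases and deacetylases, chromatin remodelers, bromodomain and PHD finger proteins, TET enzymes, Mediator subunits and nuclear receptor cofactors. The 160 members had medians of −0.52 in control and −0.31 in knockdown cells, and 106 had a centred difference above 0. The 73 members with several transcripts, which had not prompted the choice of families, had medians of −0.44 and −0.36. Random lists matched on coding length and GC content had medians of −0.18 and −0.12, and these members lay at their percentiles 0.165 and 0.18, a test chosen after the values had been seen. Histone acetyltransferase EP300 was at −1.68 in control and −0.32 in knockdown cells, its relative CREBBP at −1.32 and −0.42, the histone methyltransferase KMT2D at −1.51 and −0.25 and the remodeler subunit ARID1A at −1.60 and 0.0047, the mean of 2 transcripts, in the authors' deposited tables. EP300, CREBBP and KMT2D have 1 listed transcript each, so they are not among the 73 members. These examples were among the larger rises of the 160 members. SMARCC2 went the other way, at 0.01 and −1.97 as the mean of 3 transcripts in the authors' deposited tables. So did KDM2B, at 1.26 and −0.60 as the mean of 2 transcripts, and INO80, at −1.04 and −1.63 from 1 transcript, in the authors' deposited tables.

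The families of chromatin regulators were written down because genes with 1 listed transcript from them led the difference, so the 73 members with several transcripts served as a test of their own. Those lay at the percentile 52.9 of random lists matched on coding length and GC content, with a median of 0.06, while all members together lay at 97.9. The matched random lists had a median of 0.05, so the members with several transcripts did not stand apart from them. Such a percentile cannot tell an effect of coding length and GC content from the absence of a rise in these members. Whether these properties account for the higher values was therefore not decided. A chance choice of leading genes remains open for the members with 1 listed transcript. RBMS1 knockdown as the source of the higher values was not tested, because no values per library were held.

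Random lists matched on coding length and GC content left the mRNA decay machinery and the RNA-binding proteins, higher in the difference without passing the adjustment, at the percentiles 99.29 over 58 genes and 99.32 over 39 genes, and members with 1 listed transcript lay at 99.09 over 36 genes and 99.97 over 14 genes, which argues against these properties and against the averaging of transcripts as the whole cause. With the least changing transcript of each gene, however, the percentiles were 98.1 and 89.8. A weaker transcription block in the knockdown cells would raise the fastest-decaying genes most. The 1248 fastest-decaying genes had a median of −0.0058, with a bootstrap interval over genes of −0.033 to 0.028. That interval holds no variation between libraries. Immediate early genes, in contrast, were at 0.09 and lay at the percentile 99.2 with matching on coding length and GC content. They were taken into the rule of this test only once its result was known, which left such a block open. Variation between libraries, chance among 23 lists and the RBMS1 knockdown also stay open, untested.

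Differences of 1 or more were found in 14.7% of genes with several listed transcripts and in 5.95% of genes with 1, a ratio of 2.47. Splitting of reads between transcripts of a gene may thus contribute to the large differences. Few reads per transcript could not be settled, as the shortest of 3 bins of single transcripts held 5.28% and the longest 3.78%, a ratio of 1.40. The depth and the abundance of the transcripts, which would decide it, are unknown. A biological source of these differences was not tested.

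In a ranking of all 1024 5-mers in 3′UTRs by their correlation with the difference, corrected for 3′UTR length, A+T content, coding length and GC content, ATATA was 18 from the lowest with r of −0.0056. The highest were CCCTC, CCCCT and TCCCC, at 0.068, 0.067 and 0.066. The lowest, ACAGG, was at −0.018, so the values reached further above 0 than below it. The r of ATATA lies close to 0, and its rank was not tested. Transcripts in only the control table lay at 1 or more from 0 in 53.8% of cases and those in only the knockdown table in 60.6%, against 18.9% and 19.3% for transcripts in both.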
